A study of Homo sapiens with 15 samples.

How the data were processed

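RNA was sequenced from 15 libraries in 5 groups of 3: ACE static 72 h, ST static 48 h, ST flow 48 h, ST static 72 h and ST flow 72 h. The deposited table holds raw counts per Ensembl gene for 60623 genes, and its values are whole numbers. Per the submitters' processing notes, Trim Galore, STAR, SAMtools, bedtools and featureCounts were used with the GRCh38 genome build. Their versions, settings and annotation release are not stated, nor is whether counting used strand, so reads of overlapping and antisense genes cannot be told apart. Gene names came from a table of Ensembl identifiers and from GENCODE v29, which together named 60604 identifiers, and coordinates are GRCh38 from that release, which holds 58516 of them. Total counts ranged from 32180311 to 64954175 per library. At that depth the spread between libraries, not counting error, limits the precision for genes of moderate abundance.

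Differences were tested from the counts with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr on the 5 groups (minimum count 10), which left 17192, and libraries were scaled with TMM factors. One quasi-likelihood model with robust dispersion was fitted to all 15 libraries, with a mean per group and no replicate term. Each comparison was adjusted by the Benjamini-Hochberg method and called at 0.05. The 3 main comparisons were ST static 72 h against ACE static 72 h, and flow against static at 48 h and at 72 h. There were 3 secondary ones and a test of the difference between the flow effects at 72 h and 48 h. Levels are CPM on TMM-scaled totals. Shares of counts were compared with two-sided exact permutation tests, whose smallest p for 3 against 3 libraries is 0.1.

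Before the data were examined, 47 gene lists with 1230 entries were fixed, of which 1228 were found. Each was tested with camera (limma 3.58.1) at an inter-gene correlation of 0.01, which compares a list with all other genes, and again with an estimated correlation. With 3 libraries a group the estimated correlation takes in differences between libraries, and 0 lists passed with it for flow at 48 h or 72 h, against 20 and 21 with the preset one. For ST static 72 h against ACE static 72 h 6 of 21 lists passed with both. Counts of members that rose or fell use the adjustment over all genes unless said to be adjusted over the list alone.

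Genes to name were also chosen by a rule fixed before the data were examined. For each main comparison these were the 6 higher and 6 lower genes with the largest log2 fold change among those called, with a mean of at least 5 CPM in the higher group and no overlap between the libraries of both groups. Clone-based, long intergenic, antisense, pseudogene-like and unnamed identifiers were left out. Up to 4 members of each described list with the smallest p, any member needed for the other direction, and 17 fixed trophoblast and shear genes were added. For the secondary comparisons and the difference between flow effects the 4 higher and 4 lower were taken. Members of the CGB, PSG, MT1 and histone families are uncertain because their reads can be shared.

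The whole test was checked on simulated counts for the real genes and library sizes with 200 genes changed. As many rose as fell, none was among the least abundant genes, and the G2/M list was raised as well. All groups otherwise shared the same profile, whereas in the real data far more genes and the hCG share differed. The rates below hold for the simulated setting and may not carry over to the real comparisons. For flow at 72 h it ran on 16668 genes, recovered 36% of 2-fold and 91% of 4-fold changes, and 2.1% of its calls were false. For flow at 48 h it ran on 16641 genes and recovered 29 and 92%, and for ST static 72 h against ACE static 72 h it ran on 16587 genes and recovered 37 and 88%. For the difference between flow effects, on 16643 genes, it recovered 6 and 70%.

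Alternatives fixed in advance were RLE factors, library totals alone, no filter, a stricter filter (1 CPM), a fit without robust dispersion, a replicate block, DESeq2 1.42.0, limma-voom, fits to the compared groups alone, and leaving out each library in turn. Leaving out the 4 libraries that lay apart, removing the hCG genes before scaling, removing each library's trend with GC content and exon length, and the list test fry were added after the data were seen. No library was left out of the main results.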

Results

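The series profiled human trophoblast cells by bulk RNA sequencing to ask how fluid shear stress changes their differentiation. The cells were cytotrophoblast stem cells (nCT) obtained from naive pluripotent stem cells of 409B2, an established human induced pluripotent stem cell line. Cytotrophoblasts (CT) are the proliferating progenitors of the placenta. They fuse into the syncytiotrophoblast (ST), the layer that faces the maternal blood and secretes placental hormones. One group was kept for 72 h without flow in ACE medium, named after its A83-01, CHIR99021 and EGF (50 ng/ml), which holds the cells as progenitors. The other 4 groups were placed in ST medium, which contains 4% knockout serum replacement and 2 µM forskolin, an activator of cAMP synthesis. Those groups were kept static or under flow at 10 dyn/cm2, for 48 h or 72 h. Each of the 5 groups held 3 libraries, 15 in all, with total counts between 32180311 and 64954175 per library. Group levels below are CPM or percent of counts as mean ± SD of 3 libraries, and log2 fold changes carry their standard error. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples. Perfusion also exchanges the medium, and the labels list no static group with exchanged medium and no ACE group under flow.

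The first principal component of the 2000 most variable genes held 63.6% of the variance and ran from the ACE libraries through the static ST libraries to the ST libraries under flow at 72 h. On the third component, with 6.7% of the variance, 1 library of each ST group lay apart from the other 2 of its group. These were ST static 48 h replicate 2, ST flow 48 h replicate 1, ST static 72 h replicate 3 and ST flow 72 h replicate 1. In all 4 groups that library had the lowest share of hCG counts and the highest mean level of 7 lists, among them the interferon-stimulated, extracellular matrix and WNT target lists, and the lowest of 2, the immediate early and hypoxia lists.

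The 2 subunits of human chorionic gonadotropin (hCG), the pregnancy hormone made by the syncytiotrophoblast, took up a share of the RNA that differed between the groups. CGA, which encodes the alpha subunit (ENSG00000135346, GRCh38 chromosome 6, 87085498 to 87095406), and the CGB genes of the beta subunit together held 1.01% ± 0.411 of counts in ACE medium. Their share was 5.56% ± 2.24 in ST static 48 h, 13.8% ± 3.14 in ST flow 48 h, 10.2% ± 2.80 in ST static 72 h and 29.5% ± 2.88 in ST flow 72 h. The libraries under flow lay above the static ones at both times without overlap, with a two-sided exact permutation p of 0.1 at 48 h and at 72 h, the smallest that 3 against 3 libraries allow. The same p of 0.1 held for ST static 72 h against ACE static 72 h, and p was 0.2 (exact permutation) between the static ST groups at 72 h and 48 h. Reads of the CGB genes can be shared between near-identical copies, so values of single CGB genes are uncertain while the sum is less so.

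**Figure D1:**
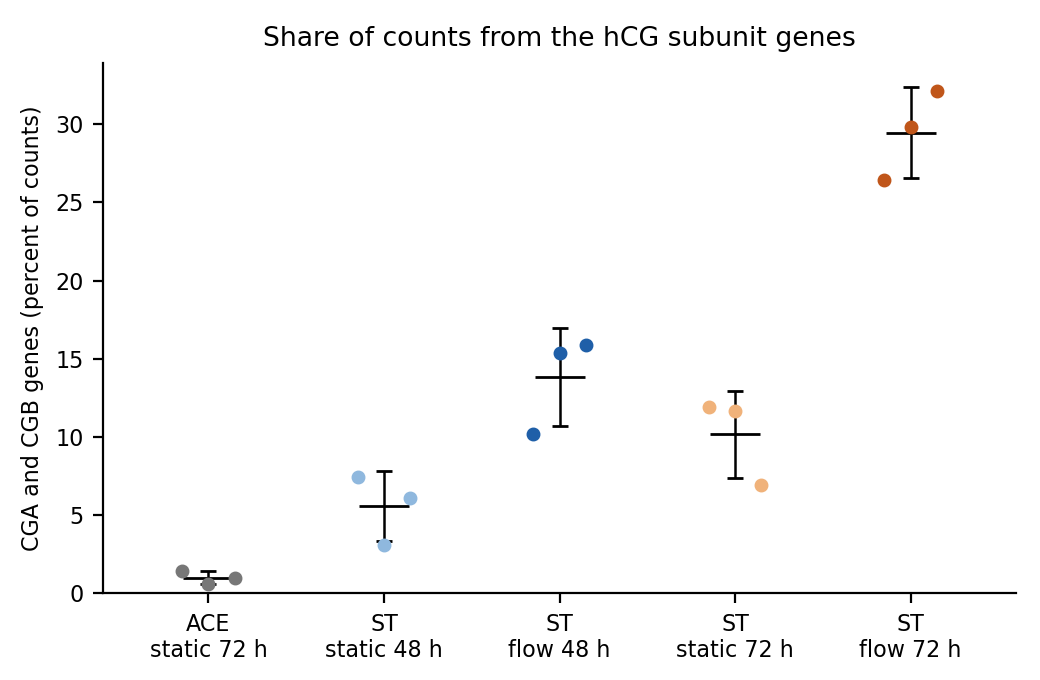
Percent of all counts that came from CGA and the CGB genes (y axis) in each library of the 5 groups (x axis), with black bars for the mean and SD of 3 libraries. The 3 ST flow 72 h libraries sit between 26.4 and 32.1%, above the 6.93 to 11.9% of the ST static 72 h libraries.

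The comparison of ST static 72 h with ACE static 72 h asked what ST medium did without flow. Hormone and identity genes of the syncytiotrophoblast were higher in ST medium than in ACE medium. Of 34 tested ST hormones and secreted factors, 29 rose and 1 fell. CGA rose by a log2 fold change of 3.60 ± 0.41 (73980 ± 22400 against 6122 ± 2304 CPM). INHA, the inhibin alpha subunit, rose by 4.72 ± 0.37, the placental insulin-like peptide INSL4 by 3.73 ± 0.25, and the adipokine gene LEP by 6.68 ± 0.80. Among 29 ST identity genes, 21 rose and 1 fell, including the heparan sulfate proteoglycan SDC1 (3.50 ± 0.34), aromatase CYP19A1 (3.04 ± 0.28) and the transcription factor TBX3 (4.16 ± 0.28). GCM1, the transcription factor that switches on the fusion genes, rose by 4.46 ± 0.25. The envelope genes ERVW-1 (syncytin-1) and ERVFRD-1 (syncytin-2), which drive cell fusion, rose by 3.61 ± 0.21 and 3.21 ± 0.44, but the fusion list went both ways, with 9 of 19 genes higher and 6 lower (10 and 6 adjusted over the list alone; camera adjusted p = 0.00157; adjusted p = 0.0393 with an estimated correlation). The hormone and identity lists also stayed past the threshold in the set test with an estimated correlation (camera adjusted p = 5.26e-16 for the hormones and 2.03e-15 for ST identity; adjusted p = 0.0393 and adjusted p = 0.0304 with an estimated correlation). Adjusted over the list alone, 29 hormones rose and 2 fell, and 23 ST identity genes rose and 1 fell.

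**Figure D2:**
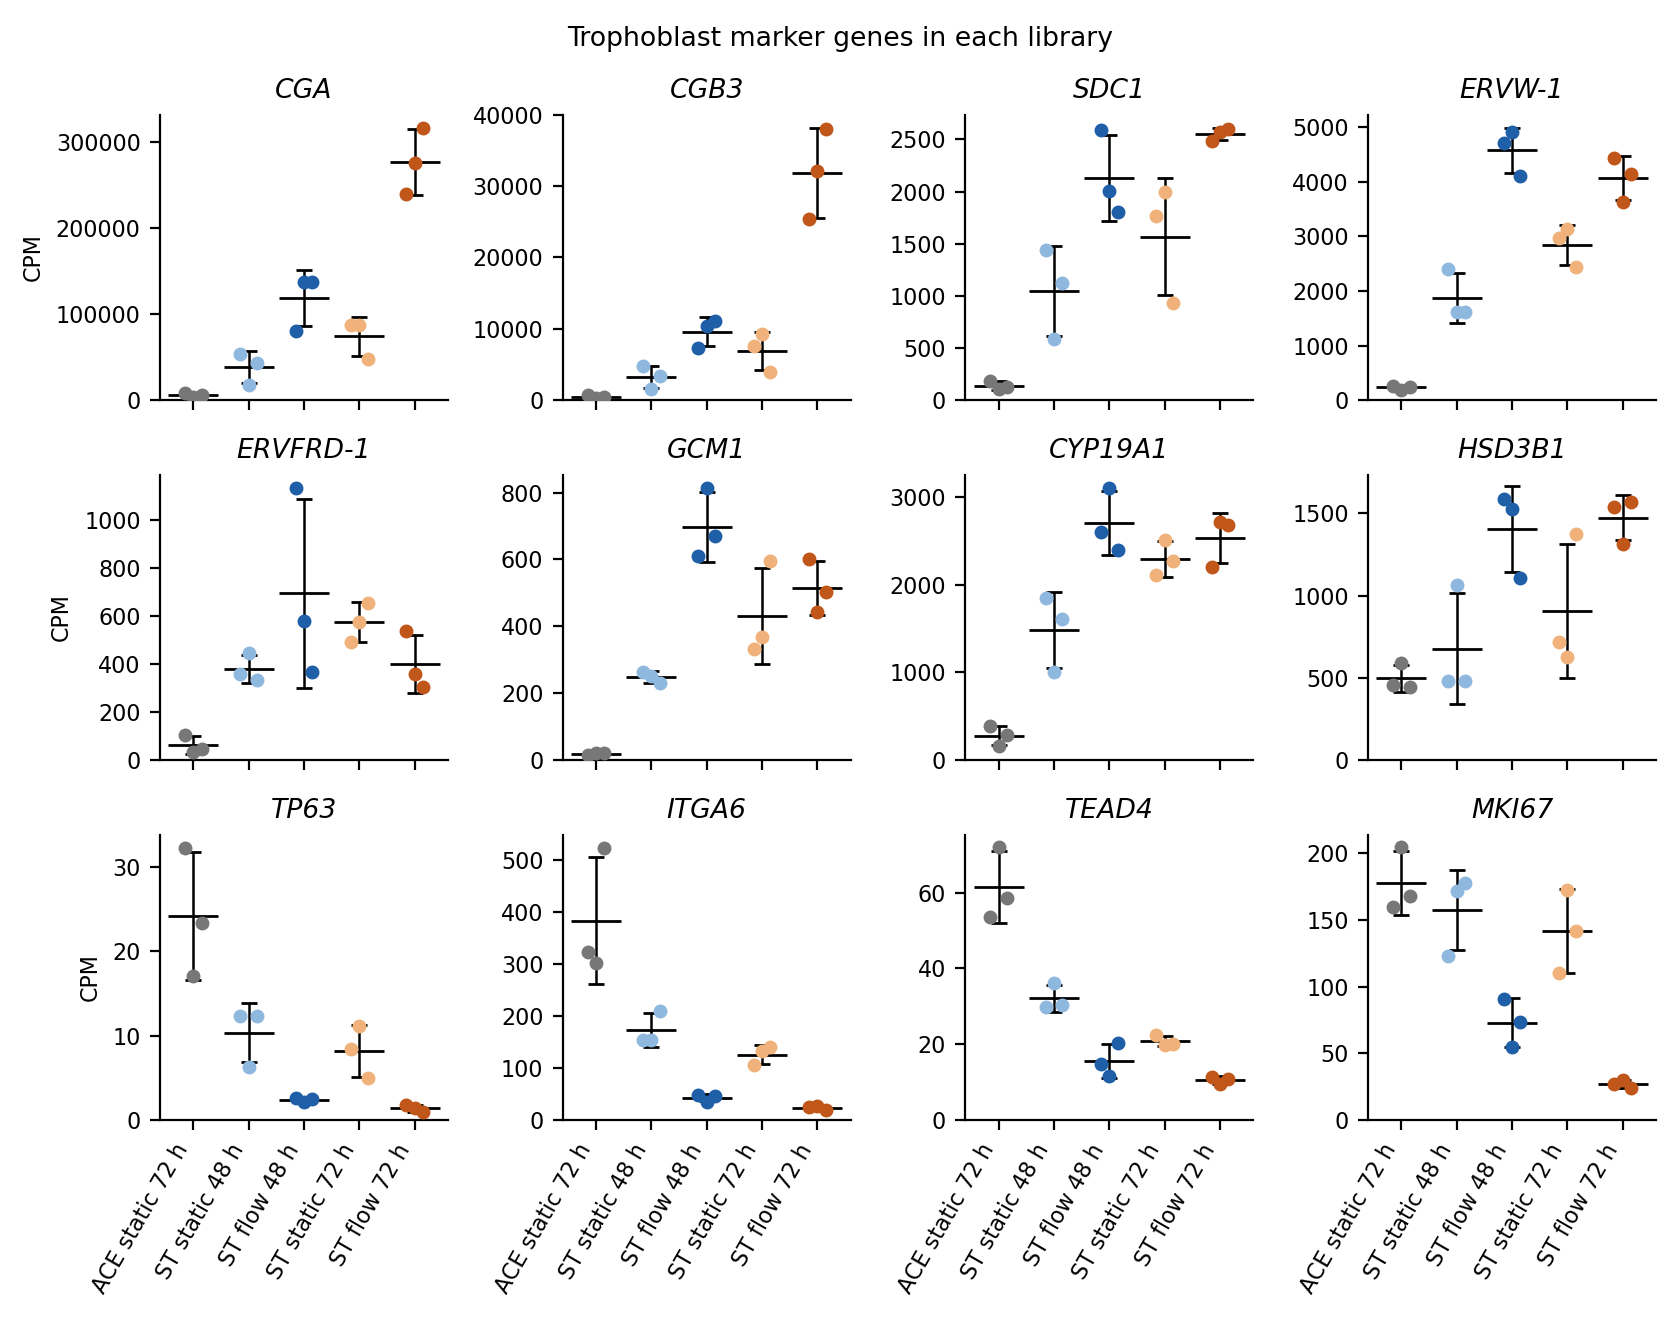
CPM (y axis, linear, from 0) of 12 trophoblast genes in each library of the 5 groups (x axis), with black bars for the mean and SD of 3 libraries. CGA averaged 276600 CPM in ST flow 72 h and 73980 CPM in ST static 72 h, while ITGA6 averaged 24.2 and 126 CPM.

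Actin cytoskeleton genes and some progenitor markers were lower in ST medium. TP63, the transcription factor of cytotrophoblast progenitors, fell (−1.56 ± 0.33), as did the laminin receptor subunit ITGA6 (−1.60 ± 0.22) and the transcription factor TEAD4 (−1.56 ± 0.20). The CT marker list as a whole went both ways, with 13 of 33 genes higher and 9 lower (camera adjusted p = 0.107), and 15 higher and 10 lower adjusted over the list alone. Of 36 actin cytoskeleton and focal adhesion genes, 22 fell and 1 rose, among them RHOC (−2.36 ± 0.22) and filamin A, FLNA (−2.10 ± 0.21). That list kept its call with an estimated correlation (camera adjusted p = 6.07e-09; adjusted p = 0.0304 with an estimated correlation; 23 lower and 1 higher adjusted over the list alone). ELF5, which marks early trophoblast, rose by 0.95 ± 0.32 (edgeR adjusted p = 0.0253), a call lost without ACE static 72 h replicate 2 or ST static 72 h replicate 1 or 2 (adjusted p 0.102, 0.103 and 0.0778) or with library totals alone (0.146). KLF2, a shear-induced transcription factor of endothelium, stood at 0.212 ± 0.0617 against 0.759 ± 0.0329 CPM, a call lost without ST static 72 h replicate 2 (edgeR adjusted p = 0.0126, and 0.053 without it). The cation channel gene PIEZO1 differed by 0.01 ± 0.22 (adjusted p = 0.963) and the proliferation marker MKI67 by −0.33 ± 0.21 (adjusted p = 0.23). KLF4 rose by 1.08 ± 0.26.

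Stress-response and cAMP target genes rose with ST medium. In the integrated stress and unfolded protein response list, 18 of 27 genes rose and 2 fell, with CEBPB at 2.58 ± 0.16, CRELD2 at 2.06 ± 0.16 and MANF at 1.79 ± 0.13. Adjusted over the list alone these were 21 and 2 (camera adjusted p = 1.48e-10; adjusted p = 0.0858 with an estimated correlation). Of 21 cAMP/CREB targets, the genes that forskolin signalling reaches through the CREB transcription factor, 12 rose and 2 fell, both over all genes and adjusted over the list alone. FOSB rose by 4.51 ± 0.32 and NR4A1 by 3.83 ± 0.36 (camera adjusted p = 1.5e-05; adjusted p = 0.0987 with an estimated correlation). In the glucose and amino acid transporter list 15 of 26 genes rose and 6 fell, with SLC38A3 at 4.99 ± 0.28 and SLC43A2 at 3.58 ± 0.24 (16 and 6 adjusted over the list alone; camera adjusted p = 0.000386; adjusted p = 0.0304 with an estimated correlation). Of 16 steroidogenesis genes 9 rose and 2 fell, the same counts adjusted over the list alone, led by CYP11A1 at 3.41 ± 0.34 and its electron donor FDX1 at 3.21 ± 0.33 (camera adjusted p = 0.00558; adjusted p = 0.186 with an estimated correlation). HSD3B1, a steroid dehydrogenase, was higher by 0.86 ± 0.32 (edgeR adjusted p = 0.0404), which was lost without ACE static 72 h replicate 1 or 3 or ST static 72 h replicate 3 (adjusted p 0.114, 0.117 and 0.264) and with RLE factors or library totals (0.0551 and 0.246).

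Genes on the lists of the invasive extravillous trophoblast (EVT) and of the interferon response were also higher. In the EVT list 13 of 28 genes rose and 4 fell, the same adjusted over the list alone, with HTRA4 at 5.04 ± 0.46 and TNS3 at 2.54 ± 0.14 (camera adjusted p = 0.000329; adjusted p = 0.0491 with an estimated correlation). HLA-G, the classical EVT antigen, did not pass (2.88 ± 0.655 against 0.542 ± 0.224 CPM, adjusted p = 0.17). Of the 28 EVT list genes 9 are also in another list, and 14 reached at least 5 CPM in ACE cells. The list alone therefore does not show an EVT program in ST medium. Of 28 interferon-stimulated genes 20 rose and none fell in the edgeR test, and 20 rose and 1 fell adjusted over the list alone, with IRF7 at 2.41 ± 0.34 and MX2 at 5.39 ± 0.98 (camera adjusted p = 0.000416; adjusted p = 0.558 with an estimated correlation). Within ST static 72 h the interferon list was highest in replicate 3, the library that lay apart on the third component. The largest increases by the naming rule were LAIR2 (ENSG00000167618, chromosome 19, 54497879 to 54510687) at 8.94 ± 0.79, HMGCS2 at 7.13 ± 0.89, MRGPRX1 at 7.12 ± 0.90, LRRC15 at 6.73 ± 0.52, LEP and ADAMTS20 at 6.20 ± 0.51. The largest decreases were SYBU at −4.89 ± 0.46, SLCO2A1 at −4.67 ± 0.98, TUBB2A and KLHL4 each at −4.57 (SE 0.37 and 0.62), TUBB2B at −4.54 ± 0.55 and CCND2 at −4.50 ± 0.89. In total 6817 of 17192 tested genes changed at an adjusted p under 0.05, 3725 higher and 3092 lower, and 4465 of them by at least 2-fold. The balance depends on scaling, since 54.6% of the calls were higher here and 33.1% with library totals alone.

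Flow was compared with static culture in ST medium, first at 48 h, to ask what shear stress added. Hormone genes and the syncytin gene ERVW-1 were higher under flow. Of 34 ST hormones and secreted factors 15 rose and none fell, among them the placental endonuclease ENDOU at 2.92 ± 0.23 (204 ± 25.3 against 26.98 ± 10.6 CPM), INHA at 2.36 ± 0.33, INSL4 at 1.90 ± 0.23 and CGA at 1.63 ± 0.38. Adjusted over the list alone 17 rose and 1 fell (camera adjusted p = 5.82e-07; adjusted p = 0.255 with an estimated correlation). Of 29 ST identity genes 13 rose and 1 fell (13 and 2 adjusted over the list alone), with GCM1 at 1.49 ± 0.23 and TENT5A at 1.53 ± 0.23 (camera adjusted p = 0.000271; adjusted p = 0.271 with an estimated correlation). ERVW-1 rose by 1.29 ± 0.19, whereas ERVFRD-1 did not pass (0.88 ± 0.41, adjusted p = 0.124). SDC1 (1.03 ± 0.31), CYP19A1 (0.86 ± 0.26) and HSD3B1 (1.06 ± 0.32) passed in the edgeR fit with adjusted p between 0.0221 and 0.0241. SDC1 did not pass without ST static 48 h replicate 2 or 3 or ST flow 48 h replicate 1 or 2 (adjusted p 0.0531 to 0.0776). CYP19A1 did not pass without ST static 48 h replicate 2 or 3 or ST flow 48 h replicate 2 (0.0501 to 0.0914), and HSD3B1 without ST static 48 h replicate 1 or 3 or ST flow 48 h replicate 1 or 2 (0.0568 to 0.0964). With library totals alone their adjusted p was 0.0578, 0.0927 and 0.2.

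Signalling and stress genes rose at 48 h as well. Of 28 immediate early and serum-response genes 11 rose and 2 fell, with IER2 at 1.64 ± 0.19 and FOSB at 1.60 ± 0.28 (15 and 3 adjusted over the list alone; camera adjusted p = 1.68e-05; adjusted p = 0.255 with an estimated correlation). That list was lowest, within each ST group, in the library that lay apart on the third component, and it passed without those 4 libraries (camera adjusted p = 0.000155). Among the integrated stress and unfolded protein response genes 14 of 27 rose and 2 fell, as they did adjusted over the list alone, including the chaperone gene DNAJC3 at 1.25 ± 0.16 and CEBPB at 1.23 ± 0.15 (camera adjusted p = 1.61e-05; adjusted p = 0.255 with an estimated correlation). Of 21 cAMP/CREB targets 7 rose and none fell, adjusted over the list alone as well, with CREM at 1.48 ± 0.18 and the phosphodiesterase PDE4D at 1.13 ± 0.20 (camera adjusted p = 0.000828; adjusted p = 0.255 with an estimated correlation). Of 25 replication-dependent histone genes 14 rose and none fell, 18 adjusted over the list alone, such as H2BC21 at 2.14 ± 0.31 and H4C9 at 1.35 ± 0.16 (camera adjusted p = 1.53e-08; adjusted p = 0.165 with an estimated correlation). Histone reads can be shared between near-identical copies, so single histone values are uncertain. The list of genes that respond to shear in endothelium did not move as a set: 6 of 28 rose and 4 fell (8 and 5 adjusted over the list alone; camera adjusted p = 0.862). In it SMAD7 rose by 1.24 ± 0.21 and ITPR3 fell by 2.16 on the log2 scale, while KLF2 (−0.80 ± 0.53, adjusted p = 0.283) and KLF4 (0.58 ± 0.26, adjusted p = 0.114) did not pass.

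Proliferation, matrix and cytoskeletal genes fell under flow at 48 h. Of 40 G2/M phase genes 32 fell and none rose in the edgeR test (33 lower adjusted over the list alone), with the centromere protein CENPF at −1.89 ± 0.20 and the mitotic kinase PLK1 at −1.67 ± 0.19 (camera adjusted p = 1.72e-20; adjusted p = 0.23 with an estimated correlation). MKI67 fell to 73.2 ± 18.1 from 158 ± 30.02 CPM. Of 40 S phase genes 11 fell and 2 rose (13 and 2 adjusted over the list alone; camera adjusted p = 0.161). Of 35 extracellular matrix genes 19 fell and 2 rose, led by perlecan, HSPG2, at −2.80 ± 0.30 and laminin LAMB1 at −2.04 ± 0.26 (20 and 2 adjusted over the list alone; camera adjusted p = 1.53e-08; adjusted p = 0.255 with an estimated correlation). The matrix list was highest, within each ST group, in the library that lay apart on the third component. Actin and focal adhesion genes fell in 18 of 36 cases and rose in 2, with MYH10 at −1.67 ± 0.19 and ACTN1 at −1.53 ± 0.23 (20 and 2 adjusted over the list alone; camera adjusted p = 1.77e-05; adjusted p = 0.23 with an estimated correlation). CT markers were lower in 13 of 33 cases and higher in 6 (15 and 8 adjusted over the list alone; camera adjusted p = 0.0234; adjusted p = 0.337 with an estimated correlation). ITGA6 fell by 1.99, TP63 by 2.10, TEAD4 by 1.04 and E-cadherin CDH1 by 1.63 on the log2 scale, and ELF5 did not pass (−0.83 ± 0.32, adjusted p = 0.0631). Of 24 mechanosensors and channels 11 fell and 3 rose, both over all genes and adjusted over the list alone, among them TRPV4 at −1.82 ± 0.29, the sodium channel subunit SCNN1A at −2.85 ± 0.56 and PIEZO1 at −0.97 ± 0.22 (camera adjusted p = 0.0237; adjusted p = 0.255 with an estimated correlation). That list did not pass with the trend of GC content and length removed (camera adjusted p = 0.0702). HLA-G was near the same level (6.09 ± 9.85 against 7.61 ± 11.7 CPM), carried by 1 library on each side: its difference was −0.32 ± 1.23, and 2.82 without ST static 48 h replicate 2. Without ST flow 48 h replicate 1 the difference was −4.23 and passed (edgeR adjusted p = 0.028), and without ST flow 48 h replicate 2 or 3 the difference was 0.23 or 0.24.

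The 6 largest increases by the naming rule at 48 h were SERPINB2 (ENSG00000197632, chromosome 18, 63871692 to 63903890) at 4.27 ± 0.48, HMGCS2 at 3.59 ± 0.68, RLBP1 at 3.33 ± 0.42, the deiodinase DIO2 at 3.22 ± 0.70, the immune receptor TREM1 at 3.16 ± 0.45 and ARHGEF37 at 3.08 ± 0.43. The largest decreases were IGFBP3, a binding protein of insulin-like growth factors, at −4.30 ± 1.09, JPH2 at −3.66 ± 0.38, HAVCR1 at −3.54 ± 0.59, NKAIN4 at −3.54 ± 0.82, FABP7 at −3.45 ± 1.12 and the WNT antagonist SFRP1 at −3.23 ± 0.41. IGFBP3 and FABP7 did not pass without ST static 48 h replicate 2 (edgeR adjusted p 0.124 and 0.307), nor FABP7 without ST flow 48 h replicate 2 or 3 (0.124 and 0.113), and with limma-voom their adjusted p was 0.0701 and 0.0717. In total 4612 of 17192 genes changed, 2089 higher and 2523 lower, and 2624 of them by at least 2-fold. Of the calls 45.3% were higher, and 14.7% with library totals alone. Without ST flow 48 h replicate 2 the count was 2990, and it was 2980 when the spread was estimated from the 6 compared libraries alone.

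Hormone genes were also higher under flow at 72 h. Of 34 ST hormones and secreted factors 23 rose and none fell in the edgeR test, 24 adjusted over the list alone (camera adjusted p = 7.53e-12; adjusted p = 0.108 with an estimated correlation). INHA rose by 3.12 ± 0.34 (1653 ± 163.9 against 190 ± 70.9 CPM), the protease inhibitor TFPI2 by 3.83 ± 0.35, the metalloproteinase PAPPA by 3.17 ± 0.46 and CGA by 1.90 ± 0.38. Of 10 pregnancy-specific glycoprotein genes 7 rose and none fell, 8 adjusted over the list alone, with PSG1 at 2.30 ± 0.21 and PSG9 at 1.30 ± 0.27 (camera adjusted p = 3.88e-05; adjusted p = 0.233 with an estimated correlation). Reads of the PSG genes, too, can be shared between copies. The ST identity list did not pass as a set, with 7 of 29 genes higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.0864). GCM1 (0.26 ± 0.22, adjusted p = 0.403), CYP19A1 (0.14 ± 0.26, adjusted p = 0.715), SDC1 (0.70 ± 0.31, adjusted p = 0.101), HSD3B1 (0.70 ± 0.32, adjusted p = 0.106) and ERVFRD-1 (−0.52 ± 0.40, adjusted p = 0.358) did not pass. HSD3B1 passed without ST static 72 h replicate 3 (edgeR adjusted p = 0.0137). ERVW-1 was higher by 0.52 ± 0.19 (edgeR adjusted p = 0.0451), and leaving out any 1 of the 6 compared libraries ended that call (adjusted p 0.052 to 0.165), as did library totals (0.804), no filter (0.131) and removal of the hCG genes (0.077). With libraries scaled by their totals alone the difference of GCM1 was −0.22 and that of CYP19A1 −0.33.

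Proliferation genes were lower across the lists at 72 h. Of 40 G2/M phase genes 39 fell, also adjusted over the list alone, and of 40 S phase genes 37 fell (38 lower and 1 higher adjusted over the list alone). The topoisomerase TOP2A fell by 2.63, CENPF by 2.55, cyclin E1 CCNE1 by 2.18 and the recombinase RAD51 by 1.96 on the log2 scale. Camera gave adjusted p = 4.83e-49 for G2/M (adjusted p = 0.0531 with an estimated correlation) and adjusted p = 7.74e-26 for S phase (adjusted p = 0.0905 with an estimated correlation). MKI67 was at 27.3 ± 2.76 against 142 ± 31.2 CPM. CT markers were lower in 18 of 33 cases and higher in 2, also adjusted over the list alone, with CDH1 at −2.37 ± 0.22, ITGA6 at −2.38 ± 0.23, TP63 at −2.54 ± 0.36, ELF5 at −1.61 ± 0.33 and TEAD4 at −0.97 ± 0.20 (camera adjusted p = 5.8e-07; adjusted p = 0.0905 with an estimated correlation). Replication-dependent histones rose in 14 of 25 cases, and none fell in the edgeR test or adjusted over the list alone, with H2BC21 at 3.21 ± 0.33 (camera adjusted p = 1.55e-06; adjusted p = 0.108 with an estimated correlation).

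Matrix, adhesion and interferon genes fell at 72 h. Of 35 extracellular matrix genes 18 fell and 1 rose, with HSPG2 at −3.17 ± 0.30, the metalloproteinase inhibitor TIMP3 at −2.39 ± 0.19 and the basement membrane collagen COL4A1 at −2.04 ± 0.19 (20 and 2 adjusted over the list alone; camera adjusted p = 1.67e-09; adjusted p = 0.234 with an estimated correlation). In the actin and focal adhesion list 19 of 36 fell and 3 rose (22 and 3 adjusted over the list alone; camera adjusted p = 3.46e-05; adjusted p = 0.108 with an estimated correlation), with CALD1 at −1.63 ± 0.18. Targets of the YAP and TAZ coactivators, which respond to tension and cell density, fell in 11 of 24 cases and rose in 2, with MYOF at −1.46 ± 0.14 and AMOTL2 at −1.77 ± 0.25 (12 and 2 adjusted over the list alone; camera adjusted p = 0.00317; adjusted p = 0.108 with an estimated correlation). Of 24 mechanosensors and channels 11 fell and 1 rose, including PIEZO1 at −1.19 ± 0.22 and PLXND1 at −1.74 ± 0.20 (12 and 2 adjusted over the list alone; camera adjusted p = 0.00158; adjusted p = 0.134 with an estimated correlation). Of 28 interferon-stimulated genes 18 fell and 1 rose (20 and 1 adjusted over the list alone), with IFIT2 at −2.64 ± 0.48 and HERC5 at −2.23 ± 0.26, while RSAD2 rose by 1.81 ± 0.30 (camera adjusted p = 3.46e-05; adjusted p = 0.406 with an estimated correlation). Of 15 WNT targets 9 fell and none rose in the edgeR test, 11 adjusted over the list alone (camera adjusted p = 0.00177; adjusted p = 0.403 with an estimated correlation). The interferon, matrix and WNT lists were among those highest, within each ST group, in the library that lay apart on the third component. Endothelial shear-responsive genes again showed no set-level difference, with 5 of 28 higher and 5 lower, also adjusted over the list alone (camera adjusted p = 0.892), although its members CYP1A1 and CYP1B1 were among the largest increases at that time. KLF2 (0.89 ± 0.55, adjusted p = 0.244) and KLF4 (0.04 ± 0.26, adjusted p = 0.92) did not pass, nor did HLA-G (−0.74 ± 1.28, adjusted p = 0.703).

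Metallothionein genes, NRF2 targets, mitochondrial transcripts and the cytochrome genes CYP1A1 and CYP1B1 rose under flow at 72 h. CYP1A1, the cytochrome P450 induced through the aryl hydrocarbon receptor (ENSG00000140465, chromosome 15, 74719542 to 74725610), rose by 6.40 ± 1.11, from 15.02 ± 9.31 to 1268 ± 179.7 CPM. CYP1B1 rose by 5.14 ± 0.92. In the list of metallothioneins, small metal-binding proteins, which also holds the zinc exporter SLC30A1, 6 of 8 tested genes rose and none fell, also adjusted over the list alone, with MT1G at 7.40 ± 1.58, MT1H at 7.38 ± 1.49, MT1X at 5.02 ± 0.95, MT1E at 4.74 ± 0.83 and MT2A at 4.27 ± 0.77 (camera adjusted p = 0.000529; adjusted p = 0.242 with an estimated correlation). The MT1 genes are near-identical copies, so their single values are uncertain. MT1G and MT1H were also scarce in static culture, at 1.23 ± 1.97 and 0.304 ± 0.526 CPM in ST static 48 h. A fold change measured from so low a level is imprecise. Of 24 targets of the oxidative stress factor NRF2, 12 rose and none fell (15 and 1 adjusted over the list alone), including ferritin light chain FTL at 1.95 ± 0.36 and the thioredoxin reductase TXNRD1 at 1.40 ± 0.27 (camera adjusted p = 0.00202; adjusted p = 0.403 with an estimated correlation). Of 15 mitochondrially encoded genes 12 rose and none fell, 14 adjusted over the list alone, with MT-ND2 at 1.94 ± 0.30 and MT-ND4 at 1.38 ± 0.24 (camera adjusted p = 1.67e-09; adjusted p = 0.242 with an estimated correlation). Their share of counts was 4.98% ± 0.151 under flow and 3.07% ± 1.35 in static culture (exact permutation p = 0.1), where ST static 72 h replicate 2 held 1.51%. Of 18 glycolysis genes 8 fell and none rose in the edgeR test or adjusted over the list alone, with PFKP at −1.85 ± 0.22 and LDHA at −1.53 ± 0.24 (camera adjusted p = 0.0121; adjusted p = 0.403 with an estimated correlation).

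By the naming rule the largest increases at 72 h were MT1G, MT1H, CYP1A1, CYP1B1, MT1X and MT1E. The largest decreases were the antiviral synthetase OAS2 at −4.97 ± 1.17, SFRP1 at −4.22 ± 0.44, EPSTI1 at −4.20 ± 1.03, IGFBP3 at −4.10 ± 1.11, PARP9 at −3.82 ± 0.62 and FAT2 at −3.73 ± 0.33. IGFBP3 did not pass without ST static 72 h replicate 3 or ST flow 72 h replicate 2 or 3 (edgeR adjusted p 0.0631, 0.0505 and 0.053) or with limma-voom (0.121). In total 5248 of 17192 genes changed, 2299 higher and 2949 lower, and 3188 of them by at least 2-fold. Of the calls 43.8% were higher, and 11.9% with library totals alone. Fold changes at 72 h rose with GC content and fell with exon length (Spearman 0.15 and −0.19 across genes, which are not independent replicates).

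**Figure D3:**
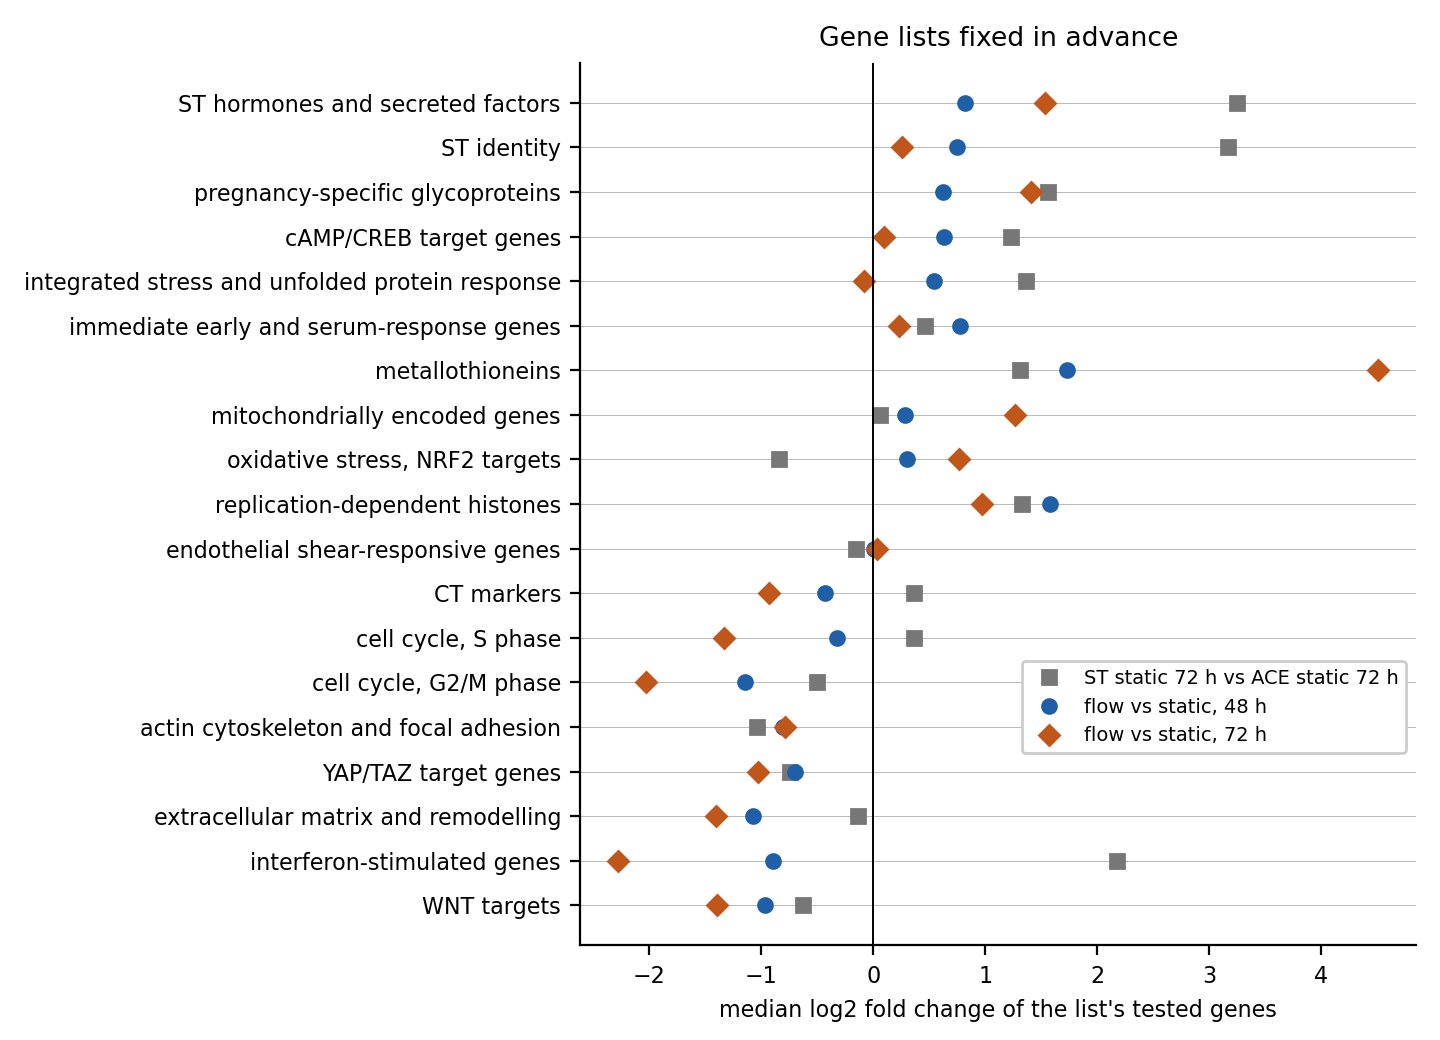
Median log2 fold change (x axis) of the tested genes of 19 lists fixed in advance (y axis), for ST static 72 h against ACE static 72 h (grey squares) and for flow against static at 48 h (blue circles) and 72 h (orange diamonds). The G2/M list had a median of −1.15 at 48 h and −2.03 at 72 h under flow, and the ST hormone list 0.82 and 1.53.

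The flow effects at the 2 times, which share no library, overlapped. Genes higher under flow at both times numbered 1081 (279.4 expected from independent lists) and genes lower at both 1640 (432.8 expected), with 51 called in opposite directions. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.63 and a Spearman rho of 0.64. A test of the difference between the 2 flow effects (edgeR, adjusted p under 0.05) called 305 genes, 72 with a higher and 233 with a lower log2 fold change at 72 h. DNA replication genes formed the largest group among the lists: 18 of 40 S phase genes had a lower flow effect at 72 h and none a higher one (31 lower adjusted over the list alone). That list passed with both correlations (camera adjusted p = 2.85e-34; adjusted p = 0.046 with an estimated correlation). EXO1 was higher under flow at 48 h (0.92 ± 0.18) and lower at 72 h (−1.34 ± 0.18), and CCNE1 went from −0.44 ± 0.16 (adjusted p = 0.0536) to −2.18 ± 0.17. The growth factor gene HBEGF turned from 1.28 ± 0.37 to −1.48 ± 0.37. The proteoglycan gene GPC3 (chromosome X, 133535745 to 133985895) went from 0.43 ± 0.54 (adjusted p = 0.592) to 4.12 ± 0.55, and PAPPA from 0.15 ± 0.46 (adjusted p = 0.844) to 3.17 ± 0.46. The call for GPC3 was lost with limma-voom (0.112) and that for PAPPA without the 4 libraries apart on PC3 (0.0657). The count of 305 moved with single libraries. It was 24 without ST flow 72 h replicate 3, 84 without ST flow 72 h replicate 2, 90, 201, 173 and 116 without ST static 48 h replicate 3 or 1 or ST flow 48 h replicate 2 or 3, and 127 and 168 without ST static 72 h replicate 2 or 3. HBEGF did not pass without ST flow 72 h replicate 3 (adjusted p = 0.0677). Neither GPC3 nor PAPPA passed without ST flow 48 h replicate 3 or ST flow 72 h replicate 2 or 3 (adjusted p 0.0597 to 0.0858). GPC3 also missed without ST static 48 h replicate 3 (0.0519), and PAPPA without ST static 48 h replicate 2, ST flow 48 h replicate 2 or ST static 72 h replicate 2 or 3 (0.0537 to 0.0619).

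To ask whether flow moved genes the way ST medium did, each flow effect was set against an ST medium effect that shared no library with it. Flow at 48 h and ST static 72 h versus ACE static 72 h changed 2630 genes in the same direction and 144 in opposite directions, with a Pearson r of 0.44 across genes (1271 higher in both against 452.6 expected, 1359 lower in both against 453.8 expected, and 49 and 95 opposite against 375.7 and 546.7 expected). Flow at 72 h and ST static 48 h versus ACE static 72 h changed 1114 genes in the same direction and 638 in opposite directions, with a Pearson r of 0.12 (511 higher in both against 344.6 expected, 603 lower in both against 295.6 expected). Of the opposite genes of that pair 167 were higher under flow, against 230.4 expected, and 471 lower under flow but higher in ST medium, against 442 expected. The 2 pairings differ in time as well as in flow, and the difference between the 2 correlations was not tested. CGA, INHA and ENDOU rose in all 3 main comparisons, and ITGA6, TP63, TEAD4 and the G2/M kinesin gene KIF23 fell in ST medium and under flow at 48 h.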

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

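The tests of removed hCG genes, of GC content and length, of S phase, of depth, of the mitochondrial share and of other splits of the libraries were chosen after related results had been seen. The place on the first component was also looked at after the data were seen. The others were fixed before their result was seen.

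The effect of flow differed between 72 h and 48 h, by a test of the difference itself, in 305 genes. Among the genes named here the log2 fold change under flow was higher at 72 h than at 48 h for GPC3 (by 3.68), PAPPA (3.02), the placental peptide genes KISS1 (2.91) and TAC3 (2.83), SYT12 (2.72), TFPI2 (2.33) and MAPRE2 (0.94). It was lower at 72 h for HBEGF (−2.75), PWWP3B (−2.66), PRR9 (−2.60), TM4SF1 (−2.38), EXO1 (−2.26), E2F8 (−2.25), ID2 (−2.11), CDC6 (−1.90), CCNE1 (−1.74), BCL2 (−1.70), SLC38A3 (−1.49), ENDOU (−1.38), RAD51 (−1.32), GMNN (−1.29), MKI67 (−1.27), RRM1 (−1.21), CALD1 (−1.07) and DNAJC3 (−0.99). CDC6, EXO1, GMNN, CCNE1, RRM1 and RAD51 serve DNA replication and repair. ID2 is on the CT marker list, but in these data it was higher in ST static 48 h than in ACE static 72 h (log2 fold change 3.61 ± 0.18). Of the 305 genes, 50 were called in opposite directions at the 2 times, 34 in the same direction, 149 at 72 h alone and 72 at 48 h alone. Most of these named calls rest on few libraries: without ST flow 72 h replicate 3, 19 of the 25 did not pass (adjusted p 0.0559 to 0.148), and without ST flow 72 h replicate 2, ST flow 48 h replicate 3 or ST static 48 h replicate 3 the number was 16, 14 and 14. With a replicate block 5 of the 25 did not pass (edgeR adjusted p 0.0513 to 0.0804), and without the 4 libraries apart on PC3 5 did not (0.0503 to 0.149). MAPRE2 was lost without any 1 of the 12 ST libraries (adjusted p 0.0519 to 0.115). In 6 of 100 regroupings of the flow labels within each time, the real one included, as many genes were called. The other 5, with 678 to 7380 genes, kept or swapped all flow labels at 1 of the times, so their counts hold the flow effect itself, a structure of the samples, and the highest, 7380, swapped flow and static at 72 h. The 85 regroupings that mixed flow and static at both times called 0 genes, but the flow effect then widens their spread. These regroupings therefore do not decide whether chance can be excluded for the 305 genes.

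For the other counts the libraries make only 10 splits each, too few for a share under 0.05. Every split but the real one also mixes libraries of both groups, so the difference between the groups widens its spread and lowers its count. These splits therefore do not decide whether chance can be excluded. The real split, 1 of the 10, was the only one to reach its own count in each of the 6 comparisons. Flow against static gave 4612 genes at 48 h and 5248 at 72 h, and ST medium against ACE medium 6817 at 72 h and 4300 at 48 h, with a highest other count of 0 in each. Under flow, 72 h against 48 h gave 1321 against a highest other count of 0, and in static culture 33 against 26.

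More genes were lower than higher under flow at 72 h, with 43.8% of calls higher. Taking the hCG genes out before scaling left 37.7% higher (95% binomial interval 36.4 to 39.0, which treats genes as independent). TMM factors already set aside genes with extreme changes, so this test had little room to raise the share. It does not decide whether the large hCG share is the cause, and the removal was not combined with library totals. A first test of GC content and gene length went with such a bias: with genes cut into tertiles, lower calls outnumbered higher ones in 4 of 6, while in the tertile with the highest GC content 1090 were higher and 764 lower, and in that of the shortest genes 927 and 491. A second test, added after that result, took out each library's trend with GC content and length and left 45.1% higher (43.7 to 46.4). This argues against that trend as the whole cause, but weakly, since the interval again treats genes as independent. GC content or length may still shape which genes were called, and scaling by library totals, under which the median log2 fold change of all genes was −0.52, gave 11.9% higher.

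Of 25 replication-dependent histone genes 14 were higher under flow at 48 h and 14 at 72 h, while most G2/M genes were lower. Neither list passed the set test with an estimated correlation at either time. The tables argue against a larger share of cells in S phase at 72 h. There the S phase list had a median log2 fold change of −1.33 (bootstrap 95% interval −1.50 to −1.25), and 37 of 40 genes fell. At 48 h the median was −0.33 (−0.48 to −0.09), but 11 of 40 fell, 2 rose and the list did not pass the set test, which leaves 48 h undecided. All bootstrap intervals here resample the genes of a set, not libraries, so they do not measure the spread between samples. The tables also argue against scaling, since at least 8 of the 14 histones called at 72 h stayed higher under 3 other scalings. Against GC content and length as the whole cause the evidence is weaker. Genes matched to those 14 had a median of 0.21 (0.12 to 0.38) against 1.48 for the 14. The 14 were picked for being called higher, which raises their median. All 25 tested histones had a median of 0.97 (0.74 to 1.34) at 72 h, still above that of the matched genes. With the trend of GC content and length removed, 9 of the 14 stayed called. More capture of RNA without a poly(A) tail in the flow libraries stays open: at 48 h 18 small noncoding RNA genes had a median of 0.80 (0.11 to 1.24), just past the bound of 0.79 set from the histone median, and at 72 h 0.88 (−0.36 to 1.40), too wide to decide. A rise of polyadenylated histone transcripts in cells that leave the cycle is a biological explanation that was not tested.

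One library of each ST group lay apart on the third principal component. Depth missed the bound of all 4 groups but stays open as the cause: that library was the shallowest in 3 of 4 groups and the deepest in the fourth. RNA quality was looked at only through the mitochondrial share of counts, which was lowest in that library in 2 of 4 groups and highest in 1. That share also missed the bound of all 4 groups. It does not measure how intact the RNA was, so RNA quality stays open. Each of these counts turns on 1 or 2 groups and is weak evidence. Less advanced ST differentiation stays open. The test set in advance, that its ST hormones without hCG be lowest in all 4 groups, was met in 3 of 4, and in ST flow 48 h the library was the highest (mean log2 CPM 4.86 against 4.57 and 4.74). But its hCG share and its place on the first component, on which ACE cells lie lowest, were lowest in all 4, the latter by little in ST flow 48 h (41.81 against 42.14 and 43.04), and ST identity was lowest and CT markers highest in 3. By the bound set in advance, the hormone result counted against less advanced differentiation, and the hCG share and first component were not part of that test. A rank among 3 libraries has no spread, so 1 group out of line does not decide, here or for depth. Cells of another type may contribute, since 2 of 8 marker lists (amnion, and mesenchyme and fibroblasts) were highest in that library in all 4 groups, but so were 7 of all 47 lists. Libraries picked at random would give 0.58 for independent lists, but these were picked for lying apart in the same data, and lists share genes. HLA-G was also highest in that library in all 4 groups (21.1, 17.5, 3.58 and 2.70 CPM in ST static 48 h, ST flow 48 h, ST static 72 h and ST flow 72 h), and the EVT list in 3. In the 4 libraries COL1A2, the most abundant mesenchyme gene, stood at 516, 363, 187 and 88.4 CPM and S100A10 of the amnion list at 394, 109, 165 and 36.4 CPM, both below their lowest ACE library (747 and 564 CPM). COL1A1, the next mesenchyme gene, was at 68.5, 52.9, 64.8 and 65.2 CPM, below the lowest ACE library (53.8 CPM) in 1 of the 4 and highest of its group in ST static 48 h and ST static 72 h alone, while the amnion list's HEY1 was at 18.3, 108, 47.3 and 116 CPM, and ACE cells expressed 4 of 15 mesenchyme and 7 of 15 amnion genes at 5 CPM or more, with 7 and 4 also in another list.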

How the results depend on the processing

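Leaving out the 4 libraries apart, removing the hCG genes, removing the GC content and length trend, and fry were chosen after seeing the data. Of 260 results for named genes 209 kept their direction and their side of the threshold under every setting. The counts with single libraries left out, and the other counts that moved by over 1.5 times, were as follows, and the cause was not tested except where fewer libraries estimated the spread. For flow at 48 h (4612) the fit to the compared groups alone gave 2980, and leaving out single libraries 2990 to 4750. Leaving out single libraries gave 3640 to 4475 for flow at 72 h, 5548 to 6247 for ST static 72 h and 2960 to 4657 for ST static 48 h against ACE. For time in static culture (33) library totals gave 1, no filter 447, DESeq2 338, limma-voom 52, the compared groups alone 0 (33 by the edgeR fit to all libraries, with 2094 at unadjusted p under 0.05), without the 4 libraries apart 91, and single libraries left out 0 to 25. For time under flow (1321) totals gave 2522, DESeq2 2000, without the 4 libraries apart 2119, and single libraries left out 431 to 1086. For the difference between flow effects (305) totals gave 490, no filter 762, DESeq2 869, without the 4 libraries apart 481, and single libraries left out 24 to 402. With a replicate block the counts were 4276, 4915, 6540, 4025, 18, 1110 and 192 in the order flow at 48 h, flow at 72 h, ST static 72 h and 48 h against ACE, static time, flow time and difference. The replicate numbers showed no pairing of libraries. Of 30 pairs with the same number 7 had a residual correlation above 0.1, and their mean was −0.015, against 0.008 for pairs with different numbers. The 4 libraries apart did correlate with each other across groups (0.106 to 0.491), but they were picked from the same data. The model holds no term for a structure shared across groups. With library totals the median log2 fold change of all genes was −0.38 for flow at 48 h, −0.52 for flow at 72 h and −0.36 for ST static 72 h, and the share of calls that were higher fell to 14.7, 11.9 and 33.1%. Medians of the ST identity list for flow at 72 h then turned from 0.26 to −0.22. With an estimated correlation the lists that passed fell to 0 for flow at 48 h and at 72 h and for static time, 6 for ST static 72 h, 3 for ST static 48 h, 3 for flow time and 2 for the difference, where fry gave 7. Of 62 list calls in the main comparisons, 6 passed under every setting. Of the 62, 56 were lost with an estimated correlation and 4 with fry. Removing the trend of GC content and length ended 7, of which only the mechanosensor list for flow at 48 h is named above. Leaving out the 4 libraries apart ended 5.

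Directions turned for genes that had not passed. HLA-G for flow at 48 h (−0.32) ran from −4.23 to 2.82 with single libraries left out. For flow at 72 h library totals gave GCM1 −0.22, CYP19A1 −0.33 and KLF4 −0.45, and KLF4 also −0.02 without a filter, −0.03 without hCG genes, −0.05 without the GC trend, and −0.07 to 0.26 with single libraries left out. PIEZO1 for ST static 72 h was −0.02 with RLE and DESeq2, −0.33 with totals, −0.03 without a filter and without the GC trend, −0.01 with the stricter filter and without hCG genes, −0.06 without the 4 libraries apart, and −0.06 to 0.06 with single libraries left out. The causes were not tested. At this depth the simulations, which changed fewer genes than the real data, recovered 6% of 2-fold differences between flow effects, so most such differences may have been missed.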

Other observations

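Cells held in ST medium for 48 h without flow already expressed the syncytiotrophoblast program, compared with ACE cells of 72 h, a comparison in which the time in culture also differs. Of 29 ST identity genes 19 rose and 1 fell (21 and 1 adjusted over the list alone; camera adjusted p = 3.94e-16; adjusted p = 0.0454 with an estimated correlation), and of 34 hormone genes 22 rose and 2 fell (24 and 2 adjusted over the list alone; camera adjusted p = 5.38e-12; adjusted p = 0.0851 with an estimated correlation). LAIR2 rose by 8.38 ± 0.79, MRGPRX1 by 6.58 ± 0.88, LRRC15 by 5.58 ± 0.49 and the WNT ligand gene WNT3A by 5.07 ± 0.36. MARCHF4 (−4.80 ± 0.56), smooth muscle actin ACTG2 (−4.50 ± 0.78), the growth factor gene FGF1 (−4.50 ± 0.76) and MYEOV (−4.45 ± 0.48) were the largest decreases by the naming rule, which asks for at least 5 CPM. In total 4300 genes changed, 2577 higher and 1723 lower.

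Between 48 h and 72 h the 2 culture conditions were followed separately. Under flow 1321 genes changed, 508 higher and 813 lower. S phase genes were lower at 72 h in 35 of 40 cases (37 adjusted over the list alone; camera adjusted p = 5.47e-49; adjusted p = 0.028 with an estimated correlation), with E2F8 at −1.84 ± 0.21, and hormone genes were higher in 17 of 34 (21 higher and 1 lower adjusted over the list alone; camera adjusted p = 3.07e-21; adjusted p = 0.0425 with an estimated correlation). GPC3 rose by 4.19 ± 0.56, the metalloproteinase ADAM12 by 3.57 ± 0.59, SYT12 by 3.57 ± 0.42 and PAPPA by 3.52 ± 0.47, while the RNA-binding protein gene LIN28A fell by 2.27 on the log2 scale. In static culture the edgeR fit called 33 genes, 31 higher and 2 lower, among them FGFBP1 at 2.36 ± 0.46, SBSN at 2.03 ± 0.36, RBM24 at 1.84 ± 0.27 and the survival gene BCL2 at 1.81 ± 0.25, with MAPRE2 (−1.10 ± 0.16) and TOMM34 (−0.92 ± 0.16) lower. Each of these 6 genes lost its call without ST static 48 h replicate 1 or 3, and the count was then 0. It was 1 without ST static 72 h replicate 2 and 10 without ST static 72 h replicate 3. The count under flow was 740 without ST flow 48 h replicate 3, 678 without ST flow 72 h replicate 2 and 431 without ST flow 72 h replicate 3. At the preset correlation camera passed 16 of 47 lists for time in static culture and 12 for time under flow. With an estimated correlation 0 and 3 passed. The smaller count of genes therefore does not show that static culture stood still. The difference between the 2 time effects is the same contrast as the difference between flow effects, which called 305 genes.

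In ST static 72 h against ACE static 72 h further groups moved. Of 47 cytosolic ribosomal protein genes 22 fell and none rose in the edgeR test, 29 adjusted over the list alone, with RPLP1 at −0.90 ± 0.14 (camera adjusted p = 0.000329; adjusted p = 0.668 with an estimated correlation). NRF2 targets fell in 11 of 24 cases and rose in 2 (12 and 2 adjusted over the list alone), with PGD at −2.09 ± 0.23 and TXN at −1.74 ± 0.16 (camera adjusted p = 0.00308; adjusted p = 0.465 with an estimated correlation). Under flow at 72 h part of that list rose, and the list did not pass there with an estimated correlation. Cell cycle genes split: 20 of 40 G2/M genes fell and 2 rose (21 and 2 adjusted over the list alone), with CDC20 at −1.61 ± 0.21, while 14 of 40 S phase genes rose and 2 fell, also adjusted over the list alone, with CCNE1 at 2.89 ± 0.17 and E2F8 at 2.81 ± 0.22. Camera gave adjusted p = 0.000386 for G2/M (adjusted p = 0.558 with an estimated correlation) and adjusted p = 0.00415 for S phase (adjusted p = 0.599 with an estimated correlation), and the S phase median of 0.36 was 0.00 with library totals. Under flow at 72 h the fusion list fell in 9 of 19 cases and rose in 3, also adjusted over the list alone, with the envelope gene ERVH48-1 at −1.95 ± 0.28 and the membrane repair gene DYSF at 1.15 ± 0.17. Its call (camera adjusted p = 0.046; adjusted p = 0.158 with an estimated correlation) was lost without ST static 72 h replicate 3 or ST flow 72 h replicate 1 (adjusted p 0.0608 and 0.0558).

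The 3 genes below were followed up after their values were seen. CYP1A1 was also higher under flow at 48 h, at 155 ± 82.3 against 24.3 ± 34.2 CPM (2.68 ± 0.94, edgeR adjusted p = 0.0466). That call was lost with RLE factors or library totals (0.051 and 0.1) and without any 1 of the compared libraries except ST static 48 h replicate 2 (adjusted p 0.0657 to 0.146). The difference between its flow effects at 72 h and 48 h, 3.72 ± 1.29, did not pass (adjusted p = 0.161). MT1G, with 38.7 ± 27.5 CPM in ST flow 72 h, averaged 9.23 ± 11.7 CPM in ST flow 48 h, where ST flow 48 h replicate 1 held 22.8 CPM. OAS2 in ST static 72 h ranged from 3.53 CPM in replicate 2 to 32.3 CPM in replicate 3.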
